A study of Caenorhabditis elegans with 2 samples.

How the data were processed

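Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out with an anti-GFP antibody on early embryos of a Caenorhabditis elegans strain that carries a SCRT-1-eGFP fusion. Per the labels, embryos were obtained by egg bleaching, were 2 h old and were used whole, and chromatin was sheared by sonication to 200 to 800 bp. The series holds 1 group of 2 biological replicates, so no comparison between conditions exists. The comparisons were between the replicates, and between reproducible sites and candidates that failed the reproducibility test.

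The deposited files are 8 peak lists in ce11 coordinates, per the labels. A list of ranked candidates and a thresholded list were deposited for each replicate alone, for the comparison of the 2 replicates with each other (the conservative list), and for a second series-wide list here called the optimal list. Each peak has a signal value from the authors' peak caller, deposited without a stated scale, and it was used only to describe and rank peaks within a list. The deposited ranked lists give the -log10 of the global irreproducible discovery rate (IDR), the expected share of irreproducible peaks among those ranked at least as high. The score deposited beside it is a capped transformation of the same IDR. The ranked list from both replicates also carries the signal and summit of the matching peak in each replicate. The control library that the labels name was not analysed here. The aligner, the peak caller and their versions are not given in the sources used here, nor is the number of reads, so the depth of each library is unknown and no interval below rests on it.

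In each deposited thresholded list the largest IDR lay just under 0.01, a stricter threshold than the 0.05 that had been assumed before the data were examined. The thresholded lists derive from a further file as well, per the submitters' file notes, and 112 peaks of the replicate comparison that reach an IDR of 0.01 are absent from the conservative list. The main results rest on the conservative list as deposited, whose peaks are called sites below. Failed candidates were the 58345 peaks of the same ranked list with a global IDR above 0.5. They passed the same peak caller and form the background of most tests.

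Summits were placed on Ensembl release 115 gene models of the same genome build, with names of non-coding genes and tRNA products taken from RefSeq. Each summit received 1 class, in the order protein-coding promoter (1000 bp upstream to 200 bp downstream of an annotated start), promoter of any other gene (pseudogenes included), coding exon, 5 prime UTR, 3 prime UTR, intron, intergenic. A class for exons of non-coding genes was added after the data were examined, because the fixed order left them without one. Classes were compared with Fisher's exact test (two-sided, Benjamini-Hochberg adjusted over the classes) and also with 1000 draws of random positions. Chromosomes were compared in the same way over the 6 nuclear chromosomes. The mitochondrial genome was left out.

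Sequences were searched on both strands within 50 bp of the summit. Each site was set against up to 5 failed candidates of the same location class with a GC content within 2 percentage points. Of the 1211 sites, 1058 had at least 1 such match and 153, with a mean GC content of 58.7%, had none and were left out. The matched sites had a mean GC content of 50.0%, their 5237 controls 49.3% and all failed candidates 38.4%. The 29 motifs and 34 gene lists were fixed before the data were examined, and all 2080 distinct 6-mers were searched as well. A gene counted as bound when a site's summit lay in the promoter window of any of its annotated starts. Gene lists were compared with all other protein-coding genes by Fisher's exact test (two-sided), adjusted over the lists.

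The analysis of sites within 100 bp of the start of a tRNA, snoRNA, snRNA or rRNA gene, together called small RNA genes below, was chosen after the data were examined; the class of non-coding promoters was fixed before. Sites named in the text are the 15 with the highest signal in the conservative list that overlap a thresholded peak of both replicates. Genes named are up to 4 bound members per fixed list with the highest promoter signal, and always scrt-1, unc-119, ces-1, snai-1 and egl-1. Other named genes and sites were chosen after their values were seen. Intervals on shares are exact (Clopper-Pearson) 95% intervals, and those on odds ratios are 95% normal intervals on the log scale. Sites, genes and windows are not biological replicates, so these intervals and p values describe these 2 libraries only.

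The tests were checked on simulated data. The E-box CAGGTG planted in 5% of 1211 windows was recovered as an excess of 3.72 percentage points (p = 7.24e-09, Fisher's exact test). With nothing planted, 0 of the 6-mers and 0 of 30 unchanged gene lists were called. Simulated sites and controls were both drawn from failed candidates without matching on location or GC content, and bound genes were drawn at random. The matching used for the real sites was thus not checked. Alternatives covered the IDR threshold, the list used, each replicate alone, the promoter window, the background and the sequence window. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.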

Results

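SCRT-1 is a C. elegans member of the Scratch branch of the Snail superfamily of zinc finger transcription factors, whose relatives bind the E-box CAGGTG and act in neural and apoptotic gene regulation. Its binding was mapped by anti-GFP ChIP-seq in whole embryos about 2 h old, in 2 biological replicates. The conservative list holds 1211 reproducible sites (1156 after merging overlapping peaks), with a median width of 316 bp and a median signal of 94.6. They were drawn from 101059 ranked candidates. The optimal list holds 1244 sites, 957 of which have the same coordinates as a conservative site, and the longer of the 2 series lists exceeded the shorter by a factor of 1.03.

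The first comparison asked how far the replicates found the same places. Sites at tRNA, snoRNA and snRNA genes, pooled, lay in both replicates' own thresholded lists more often than the other sites. This held for 219 of 317 sites at such small RNA genes (69.1%, 95% interval 63.7 to 74.1), against 154 of the 894 other sites (17.2%, 14.8 to 19.9). Signal was also higher at small RNA genes (quartiles 115 and 289, against 77.0 and 107 at the other sites). The shares were not compared at equal signal, so they do not show better recurrence at a given signal. Replicate 1 alone gave 564 thresholded peaks and replicate 2 gave 522. After merging, 368 of the 547 peaks of replicate 1 overlapped a peak of replicate 2 by at least 1 bp (67.3%, 63.2 to 71.2), where random placement gave a mean of 0.283% and at most 1.10% in 1000 draws (p = 0.001, the smallest these permutations can give). In the other direction 367 of 512 peaks of replicate 2 overlapped (71.7%, 67.6 to 75.5). Against all ranked candidates of replicate 2, 97.4% of replicate 1 peaks overlapped, with 27.9% by random placement.

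Signal ranked alike in both libraries at small RNA genes (Spearman rho 0.892 over 317 sites) and less so at the other 894 sites (rho 0.360). Signal also spread more widely at small RNA genes, and rho was not compared over an equal range of signal. Over all 101059 candidates rho was 0.283, and over the 1211 sites it was 0.625. Sites were selected for agreement of their ranks between the replicates, so the values over sites are conditional on it, and sites are not independent replicates. The summits of the paired replicate peaks lay a median of 15 bp apart at small RNA genes and 30 bp apart at the other sites. Of the 1211 sites, 594 (49.1%, 46.2 to 51.9) lay in neither replicate's own thresholded list and entered through the comparison of the 2 replicates.

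Where the sites lie was the second comparison. Genes transcribed into short structured RNAs stood out. Of the 612 nuclear tRNA genes, 252 had a site within 100 bp of the start (41.2%, 37.2 to 45.2), as did 58 of 346 genes for snoRNAs, which guide RNA modification (16.8%, 13.0 to 21.1), and 12 of 129 snRNA genes, which include spliceosomal RNAs (9.30%, 4.90 to 15.7). By contrast, 95 of 19973 protein-coding genes had a site that close to a start (0.476%, 0.385 to 0.581). None of the 20 annotated nuclear rRNA genes did, which allows a share of up to 16.8%. All 252 bound tRNA genes held a 30-mer found elsewhere in the genome, so reads shared between gene copies stay open as a source of their sites. Sites at tRNA genes made up 250 of the 1211 (20.6%), against 0.0754% of failed candidates (odds ratio 345, 249 to 478). For snoRNA genes the odds ratio was 65.4 (44 to 97.4, adjusted p = 1.37e-68, Fisher's exact test). The share of sites at small RNA genes depended on the list. It was 26.2% in the conservative list, 47.9% without replicate 1, 47.3% without replicate 2, 58.6% at an IDR of 0.001 and 11.2% at an IDR of 0.05.

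**Figure D1:**
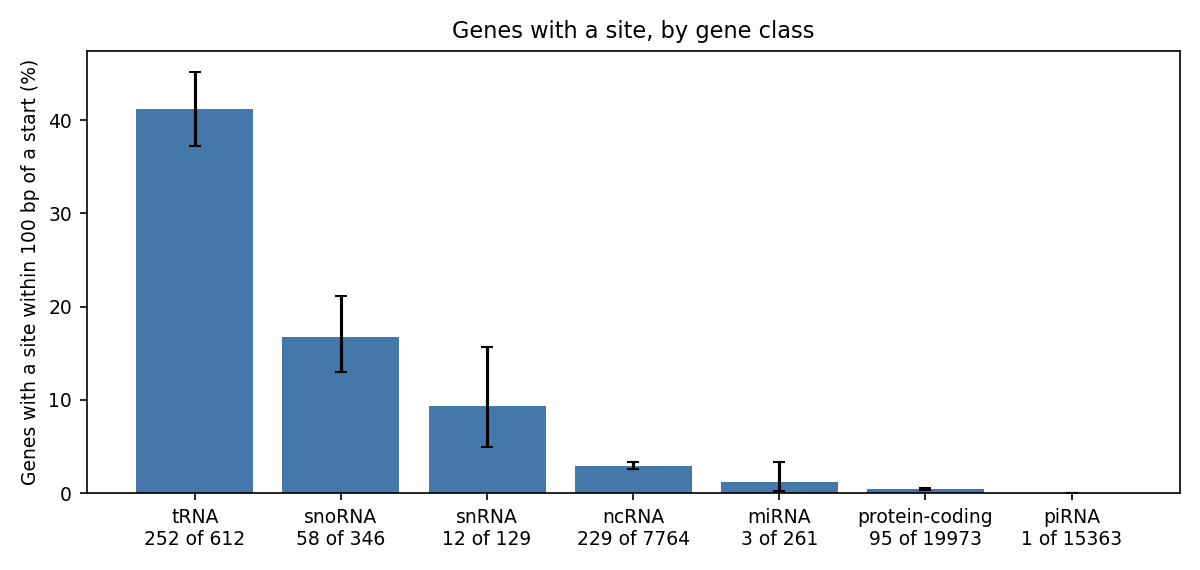
Percent of annotated genes with a site within 100 bp of a start, by gene class on the horizontal axis, with 95% exact intervals as error bars. tRNA genes reach 41.2% and snoRNA genes 16.8%, and protein-coding genes 0.476%.

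These genes also carried the highest signals. Of the 100 strongest sites, 50 lay at tRNA genes and 32 at snoRNA genes. The median signal was 177 at small RNA genes and 86.5 at the other sites. Summits sat mostly inside the tRNA genes, a median of 20 bp downstream of the annotated start (quartiles 8 and 33), where tRNA genes hold their internal promoter. At snoRNA genes they sat upstream, at a median of -45 bp (quartiles -53 and -34). All 20 tRNA families with at least 10 genes held bound members, from 30.8% of the tRNA-Ser genes to 61.5% of the tRNA-Cys genes. No family differed from the rest (smallest adjusted p = 0.963 and smallest unadjusted p = 0.159, Fisher's exact test).

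**Figure D2:**
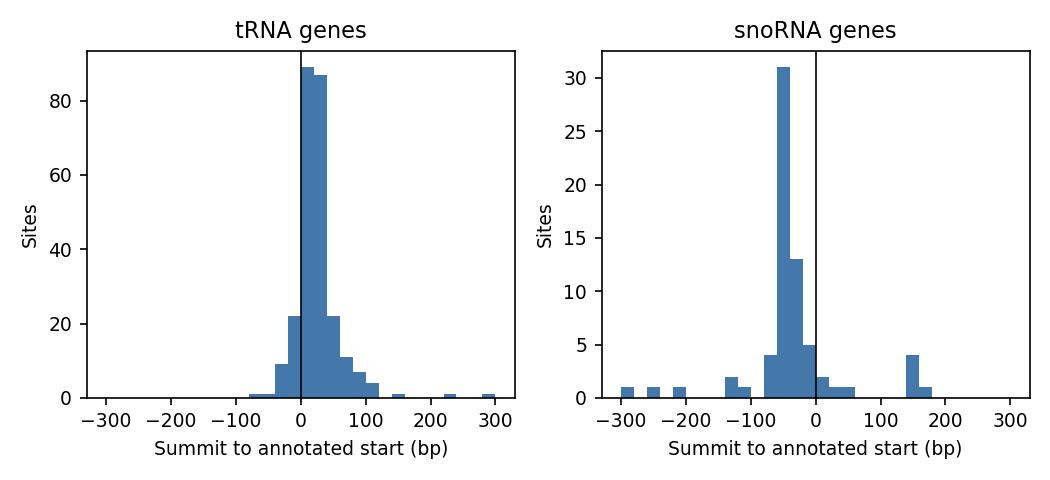
Number of sites by distance in bp from the summit to the annotated start of the nearest tRNA gene (left) or snoRNA gene (right), in 20 bp bins, with positive values downstream of the start. tRNA summits centre on 20 bp and snoRNA summits on -45 bp.

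Of the 15 strongest sites found in both replicates, 9 lay within 100 bp of a snoRNA gene start, 3 at tRNA genes and 1 at another non-coding RNA gene. The strongest, on chromosome V from 12303483 to 12303784, had a signal of 993 (574 in replicate 1 and 422 in replicate 2) and lies inside frm-7, 38 bp into the snoRNA gene C51F7.4. The next, on II from 11960681 to 11960989 (signal 921), lies between genes, 60 bp upstream of the snoRNA gene W03C9.9, with W03C9.1 as the nearest protein-coding gene. The third, on I from 8259432 to 8259705 (signal 789), falls in the promoter window of the chemoreceptor gene sre-23 and 75 bp upstream of the snoRNA gene ZK265.10. The remaining snoRNA sites lie near str-56, inside cutl-18, pxn-1 and Y43F8C.7, and in the promoter windows of T02E1.2 and wrt-3, a hedgehog-related gene. tRNA sites include a tRNA-Leu gene near C04A11.5 (X from 13665441 to 13665725, signal 657), a tRNA-Cys gene inside cye-1, which encodes cyclin E (I from 6781693 to 6781942, signal 533), and a tRNA-Lys gene near the collagen gene col-181 (X from 12106077 to 12106339, signal 501). The site nearest hrg-5 lies 20 bp into the non-coding RNA gene F36H1.17 (IV from 11025954 to 11026345, signal 590). The 2 others had no annotated gene start of any kind within 100 bp: 1 lies 530 bp upstream of K12H4.5 (III from 8043860 to 8044079, signal 614), the other in an intron of cmk-1, which encodes a calmodulin-dependent kinase (IV from 1831265 to 1831500, signal 568).

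By location class, promoters were over-represented. Protein-coding promoter windows held 471 of 1211 summits (38.9%, 36.1 to 41.7) against 25.9% of failed candidates (log2 odds ratio 0.87, adjusted p = 2.59e-22, Fisher's exact test). Promoters of non-coding genes held 361 (29.8%, 27.2 to 32.5) against 9.96% (log2 odds ratio 1.94, adjusted p = 7.32e-79, Fisher's exact test). Coding exons (7.93% against 21.0%), introns (10.1% against 25%), intergenic DNA (11.6% against 14.3%) and 3 prime UTRs (0.908% against 1.89%) held fewer, with adjusted p of 2.25e-34, 1.36e-38, 0.00977 and 0.0129 by Fisher's exact test. In the replicates' own lists the shares were lower still, with coding exons at 1.34% without replicate 1 and 1.95% without replicate 2, and 3 prime UTRs at 0 in both. For 5 prime UTRs (0 sites, adjusted p = 0.126) and non-coding exons (odds ratio 0.527, adjusted p = 0.0500088) the test, Fisher's exact test, was not passed. Non-coding exons did pass as lower with merged peaks, in either replicate's own list, at an IDR of 0.001 and 0.05, and with the 500 bp promoter window, at odds ratios from 0.112 to 0.558. Without the small RNA gene sites, 43.5% of 894 summits lay in protein-coding promoters, while the log2 odds ratio of non-coding promoters was 0.57 (adjusted p = 0.000205, Fisher's exact test). In that setting intergenic DNA was no longer lower (15.7% against 14.3%, odds ratio 1.11, 0.927 to 1.33), and the 3 prime UTR call was lost (odds ratio 0.648, 0.356 to 1.18). The intergenic call of the main comparison also rests on which peaks the conservative list holds. Of the peaks that reach an IDR of 0.01 but are absent from it, 80.4% were intergenic. Failed candidates were taken from the ranked list, where no peaks were absent in this way. The main comparison therefore cannot show whether reproducible peaks as a whole are fewer in intergenic DNA.

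**Figure D3:**
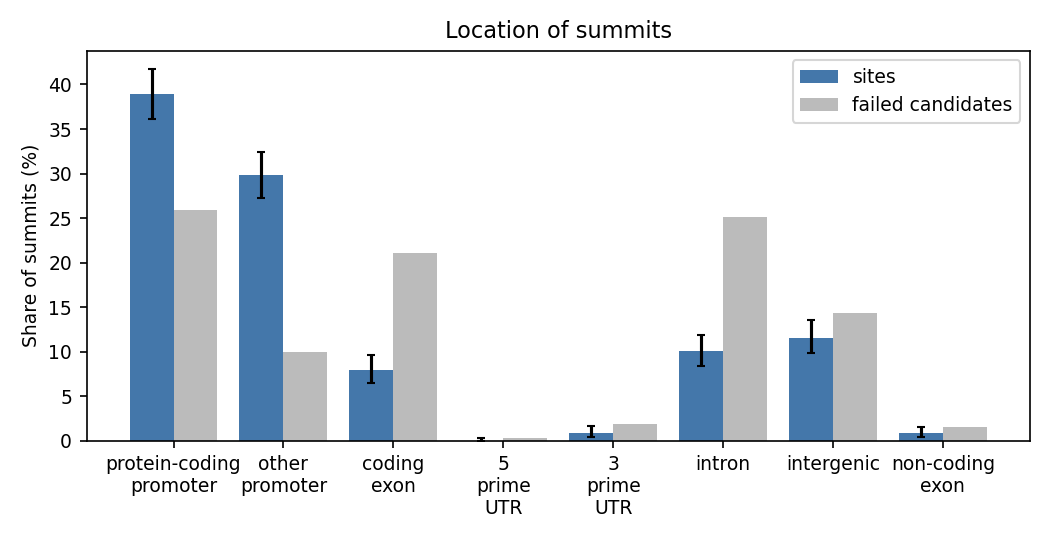
Percent of summits in each location class, for the 1211 sites (with 95% exact intervals) and the 58345 failed candidates. Both promoter classes are higher among sites (38.9% against 25.9%, and 29.8% against 9.96%), and coding exons and introns are lower.

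Chromosome X held the most sites, 260 of 1211 (21.5%), against 16.8% of failed candidates (odds ratio 1.35, 1.18 to 1.55, adjusted p = 0.000162, Fisher's exact test). Chromosome V held 182 (15% against 19.6%, odds ratio 0.727, 0.621 to 0.853, adjusted p = 0.000162, Fisher's exact test). Chromosomes I, II, III and IV did not pass the test, with adjusted p from 0.253 to 0.785, although I passed as higher at an IDR of 0.05 (odds ratio 1.26, 1.15 to 1.38) and without replicate 2 (1.28, 1.04 to 1.58). Against chromosome length instead, I and III held more sites than their share and IV fewer (adjusted p = 0.0323, 0.00260 and 5.44e-05, exact binomial test). X also holds 276 of the 612 tRNA genes (45.1%). Away from small RNA genes the X excess was not detected (log2 odds ratio 0.06, adjusted p = 0.745), and it was not detected at an IDR of 0.05 either (log2 odds ratio 0.06, adjusted p = 0.459, Fisher's exact test).

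The third comparison asked which sequences mark the sites. CAGGTG, the E-box bound by Snail and Scratch proteins, was not enriched against matched failed candidates. It occurred within 50 bp of the summit in 38 of 1058 matched sites (3.59%) and in 245 of 5237 matched failed candidates (4.68%), an odds ratio of 0.759 (0.536 to 1.08, p = 0.123, Fisher's exact test). The extended form RCAGGTG (odds ratio 0.838, 0.546 to 1.29) did not differ detectably from these controls either, but was more frequent than in the flanks of the same sites (2.31% against 1.16%, odds ratio 2.02, 1.19 to 3.43, adjusted p = 0.0259, Fisher's exact test). Flanks were not matched on GC content, and against them the control word CACCGG (odds ratio 2.59, 1.68 to 3.99) and GGGCGG (odds ratio 6.21, 4.32 to 8.93) rose more, so this rise is not specific to the Scratch site. Of the 29 fixed motifs, 3 were more frequent in sites, at an adjusted p under the threshold by Fisher's exact test. The GAGA repeat GAGAGA occurred in 13.5% of sites and 9.62% of controls (odds ratio 1.47, adjusted p = 0.00348), the E-box variant CAAGTG in 7.75% and 4.98% (odds ratio 1.60, adjusted p = 0.00579), and the GC box GGGCGG of Sp1 and KLF proteins in 9.07% and 6.47% (odds ratio 1.44, adjusted p = 0.0196, Fisher's exact test). The splice acceptor TTTCAG (6.33% against 10.1%, adjusted p = 0.00202) and the Sox motif ACAAWG (6.14% against 8.92%, adjusted p = 0.0196, Fisher's exact test) were less frequent. Both calls were lost without small RNA gene sites (odds ratios 0.712, 0.545 to 0.931, and 0.722, 0.542 to 0.961). TTTCAG was also lost against dinucleotide shuffles (0.876, 0.675 to 1.14) and ACAAWG at an IDR of 0.05 (0.819, 0.704 to 0.952). The calls for GAGAGA and CAAGTG were lost in either replicate's own list, where the odds ratios were 1.13 (0.840 to 1.52) and 1.3 (0.881 to 1.90) without replicate 1, and 1.28 (0.962 to 1.71) and 1.13 (0.756 to 1.69) without replicate 2. At an IDR of 0.001 GAGAGA was lost as well (odds ratio 1.08, 0.756 to 1.54). CAAGTG was also lost with the optimal list (odds ratio 1.40, 1.07 to 1.84), with merged peaks (1.42, 1.09 to 1.86), over the whole peak (1.10, 0.914 to 1.32), and at an IDR of 0.001 (1.61, 1.04 to 2.5) and 0.05 (1.20, 1.01 to 1.43), with adjusted p from 0.0596 to 0.432 by Fisher's exact test. GGGCGG kept its call in both replicate lists and lost it at an IDR of 0.05 (odds ratio 1.23, adjusted p = 0.124, Fisher's exact test) and with merged peaks (odds ratio 1.36, adjusted p = 0.0596, Fisher's exact test). Some motifs passed only under alternatives. The EOR-1 word GAGACGCAG (odds ratio 1.33, 0.842 to 2.09 in the main comparison) passed as higher within 100 bp of the summit (1.57), over the whole peak (1.90), against flanks (5.29) and against shuffles (33.2). CAACTG passed as higher without replicate 1 (1.70) and at an IDR of 0.001 (1.98), and the SKN-1 word RTCATC and the GATA word WGATAR passed as lower under several, at odds ratios from 0.411 to 0.797 and from 0.434 to 0.811. The control word CACCGG also passed as lower without replicate 1 (odds ratio 0.285, 0.132 to 0.616, adjusted p = 0.00343, Fisher's exact test). A call under an alternative can therefore fall on a control word.

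Without preset motifs, 206 of all distinct 6-mers were more frequent in sites and 160 less frequent after adjustment. The leading ones were CGAACC (11.6% of sites and 3.59% of controls, odds ratio 3.53, 2.79 to 4.48) and ACCACT (14.2% and 5.37%, odds ratio 2.91). GTTCGA followed (12% and 4.70%, odds ratio 2.77). It belongs, like CGAACC read on the other strand, to the B box of the internal tRNA promoter. These shares are those of the 1058 matched sites. Over all 1211 sites CGAACC occurred in 172 (14.2%), so the sites left out for want of a match held it more often. With small RNA gene sites left out, 91 6-mers were more frequent, 82 of which were among the 206. The leading ones were then GCGCAC (11.1% of 872 sites and 3.90% of 4329 controls, odds ratio 3.08, 2.37 to 4.0), CGCGCA (11.2% and 4.37%, odds ratio 2.77) and GCGCGC (9.52% and 3.83%, odds ratio 2.64).

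The fourth comparison concerned the 597 protein-coding genes (2.99% of 19973) with a site in their promoter window. Histone genes, cytosolic ribosomal protein genes and splicing genes were bound more often than other genes. Without the control library, signal at any highly transcribed gene cannot be told apart from specific binding in these lists. Histone genes reached 14 of 50 (28.0%, odds ratio 12.9, 6.92 to 24.0, adjusted p = 4.62e-09, Fisher's exact test), at 12 sites, since neighbouring histone genes share promoters. In either replicate's own list 5 were bound (10%), at odds ratios of 7.77 (3.06 to 19.7) without replicate 1 and 7.60 (3.00 to 19.3) without replicate 2, and the call was kept. They include his-31 (site on IV from 8334415 to 8334533, signal 156), his-67 and his-68, which share a site on I from 9988861 to 9989176 (signal 137), and his-17 (signal 101). Near-identical histone gene copies can share reads, so the position of such a site is uncertain. Ribosomal protein genes reached 13 of 78 (16.7%, odds ratio 6.61, 3.63 to 12.1, adjusted p = 5.62e-06, Fisher's exact test), led by rpl-3 (267 bp upstream of the start on III, signal 271), rpl-15 (186), rpl-20 (168) and rps-28 (152). All 4 were in the thresholded lists of both replicates. Splicing genes reached 6 of 33 (18.2%, odds ratio 7.28, 2.99 to 17.7, adjusted p = 0.00329, Fisher's exact test), among them the Sm protein gene snr-1 (signal 136), prp-19 (108), prp-31 (107) and rsp-1 and rsp-2, which share a site (91.8). None of the histone and ribosomal protein sites and 1 of the 5 splicing gene sites lay at a small RNA gene. In either replicate's own list 3 splicing genes were bound and the call was lost, at odds ratios of 6.95 (2.11 to 22.9) without replicate 1 and 6.80 (2.06 to 22.4) without replicate 2 (adjusted p = 0.0981 and 0.104, Fisher's exact test). It was also lost at an IDR of 0.001 (odds ratio 3.12, 0.424 to 22.9) and with the nearest start within 5000 bp (odds ratio 2.68, 0.941 to 7.65), where the ribosomal protein call was lost too (odds ratio 2.23, 1.07 to 4.64, adjusted p = 0.239, Fisher's exact test). At an IDR of 0.001 the histone call was also lost (odds ratio 6.42, 1.98 to 20.8, adjusted p = 0.154, Fisher's exact test).

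**Figure D4:**
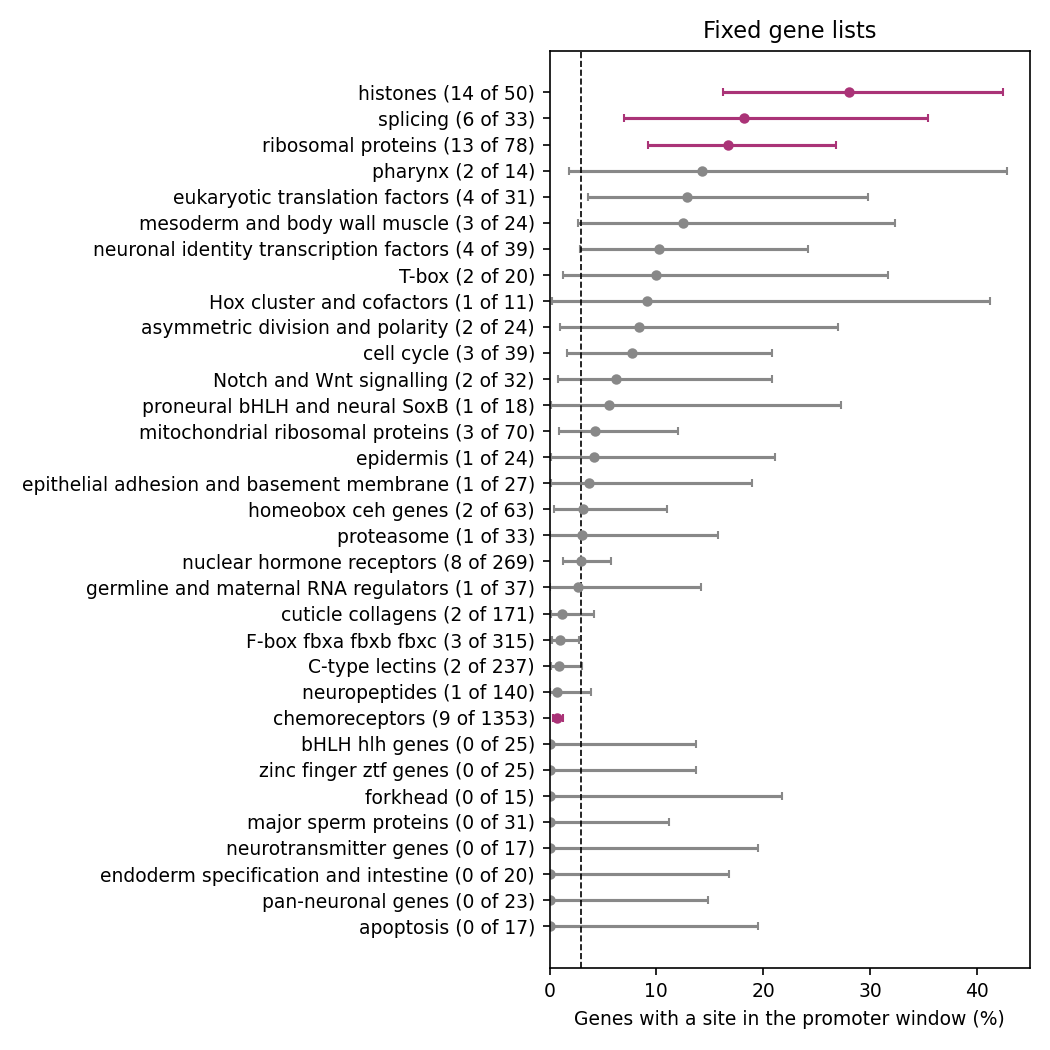
Percent of the genes of each fixed list (those with at least 10 genes) with a site in the promoter window, with 95% exact intervals. Coloured points passed the adjusted test, and the dashed line marks the 2.99% of all protein-coding genes; histones (28.0%), splicing genes (18.2%) and ribosomal proteins (16.7%) lie above it, and chemoreceptors (0.665%) below.

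Chemoreceptor genes, which are expressed mainly in sensory neurons, were bound less often, 9 of 1353 (0.665%, odds ratio 0.205, 0.106 to 0.398, adjusted p = 2.40e-08, Fisher's exact test). The strongest were sre-23 (signal 789), sre-1 (265), srh-269 (160) and srd-44 (129), and 3 of the 8 sites at these 9 genes lay at small RNA genes. This call was not passed at an IDR of 0.001 (odds ratio 0.280, 0.104 to 0.755, adjusted p = 0.0694, Fisher's exact test).

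Lists tied to the known roles of the Snail superfamily did not pass the test. None of the 17 apoptosis genes, 23 pan-neuronal genes or 17 neurotransmitter genes was bound, which allows shares of up to 19.5%, 14.8% and 19.5%. Of 39 neuronal identity transcription factors 4 were bound (odds ratio 3.73, 1.32 to 10.5, adjusted p = 0.138, Fisher's exact test), a rise that did not pass after adjustment. These were daf-19, the RFX factor of ciliated neurons (signal 141), and the homeobox genes ceh-34 (89.1), ttx-1 (88.4) and unc-30 (82.1). Of 18 proneural and SoxB genes 1 was bound, sox-2 (82.8, adjusted p = 0.795, Fisher's exact test). Muscle genes gave 3 of 24, unc-27 (troponin I, 91.1), unc-15 (paramyosin, 82.5) and tbx-38 (79.4). Their odds ratio was 4.65 (1.38 to 15.6, adjusted p = 0.143, Fisher's exact test). Of 14 pharynx genes 2 were bound, tbx-2 (111) and peb-1 (109), at an odds ratio of 5.42 (1.21 to 24.3, adjusted p = 0.218, Fisher's exact test). The sites of sox-2, unc-27 and peb-1 also lay 33, 57 and 57 bp from the start of a gene annotated as ncRNA. Which gene these sites belong to is therefore uncertain. In all, 30 of the 34 lists did not pass, 9 of them with no bound gene. Over all 34, 8 had an unadjusted p under 0.05, the called lists included.

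A few genes of other lists also had promoter sites. Among 39 cell cycle genes these were lin-35, the Retinoblastoma homologue (signal 97.2), the cell cycle inhibitor cki-1 (87.4) and cya-1 (cyclin A, 85.6). Wnt pathway genes were mom-1 (Porcupine, 406, at a small RNA gene) and lit-1 (a Nemo-like kinase, 90.7). At an IDR of 0.05 both lists passed the test as higher, with 7 of 39 cell cycle genes (odds ratio 3.39, 1.49 to 7.68, adjusted p = 0.0411, Fisher's exact test) and 7 of 32 Notch and Wnt genes (odds ratio 4.33, 1.87 to 10, adjusted p = 0.0183). Polarity genes were cgef-1 (78.8) and pkc-3 (68.4, 54 bp from the start of a gene annotated as ncRNA). The maternal regulators gave mex-1 (105), the Hox cofactors unc-62 (69.6) and the epidermal and junction lists ajm-1 (113, at a small RNA gene). Translation factors gave 4 of 31, eif-3.C (206), eif-2Bgamma (140), eif-3.E (83.7) and eef-1G (59.2), the second of them at a small RNA gene, with an adjusted p of 0.0891.

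The remaining families had adjusted p values of at least 0.138. Nuclear hormone receptors gave 8 of 269, led by nhr-255 (372) and nhr-41 (304), both at small RNA genes, nhr-95 (99.7) and nhr-142 (91.8). F-box genes gave 3 of 315, fbxc-44 (152), fbxb-58 (120) and fbxb-85 (111), and passed the test as lower at an IDR of 0.05 (odds ratio 0.398, 0.197 to 0.804). C-type lectins gave clec-126 (262) and clec-53 (156), collagens col-185 (225) and col-71 (87.0, list odds ratio 0.382, 0.0945 to 1.54), neuropeptides flp-23 (270), homeobox genes ceh-2 (87.5) beside ceh-34, and T-box genes tbx-2 and tbx-38. The sites of clec-126, col-185, flp-23, ceh-2 and mrpl-23 lay at small RNA genes. With the nearest start within 5000 bp, collagens turned to higher and passed (odds ratio 2.91, 1.85 to 4.57), and F-box genes (0.184, 0.0589 to 0.575) and C-type lectins (0.246, 0.0788 to 0.771) passed as lower. Mitochondrial ribosomal protein genes gave mrpl-23 (242), mrpl-39 (121) and mrpl-12, and the proteasome list rpn-7 (116). Endoderm and intestine genes, bHLH genes, forkhead genes, ztf zinc finger genes and major sperm protein genes had no bound member.

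The last comparison concerned the loci that the transgene carries. The gene scrt-1 (chromosome I from 2568860 to 2571059) lies in a stretch of 51 kb, from 2533953 to 2584903, in which the ranked list of both replicates has no candidate, where the genome average would give 51.4. The ranked list of replicate 1 has 1 candidate there and that of replicate 2 has 0. Within 20 kb of scrt-1 there were 10 candidates, 0.237 per kb, against a median of 1.04 per kb around 1000 random protein-coding genes, 5.1% of which had as low a density. The gene unc-119, whose wild-type copy serves as the transformation marker (III from 10902641 to 10908935), had 54 candidates within 20 kb (1.17 per kb, percentile 62.3). It held 3 sites near its 3 prime end, on III from 10907955 to 10908270 (signal 143, coding exon), 10908226 to 10908541 (34.8, intron) and 10908507 to 10908822 (135, coding exon). These 3 intervals overlap end to end, and the first 2 were paired with the same replicate peaks (signals 69.9 and 84.1). Counted apart, they gave a density of sites that 97.3% of random genes equalled or fell below. The genes snai-1 and egl-1, with 1 site each within 20 kb, stood at percentiles 78.9 and 87, so the rank of unc-119 depends on counting overlapping peaks apart. Transgene copies were not counted here, so the sites at unc-119 were not taken as evidence of occupancy of the native gene.

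**Figure D5:**
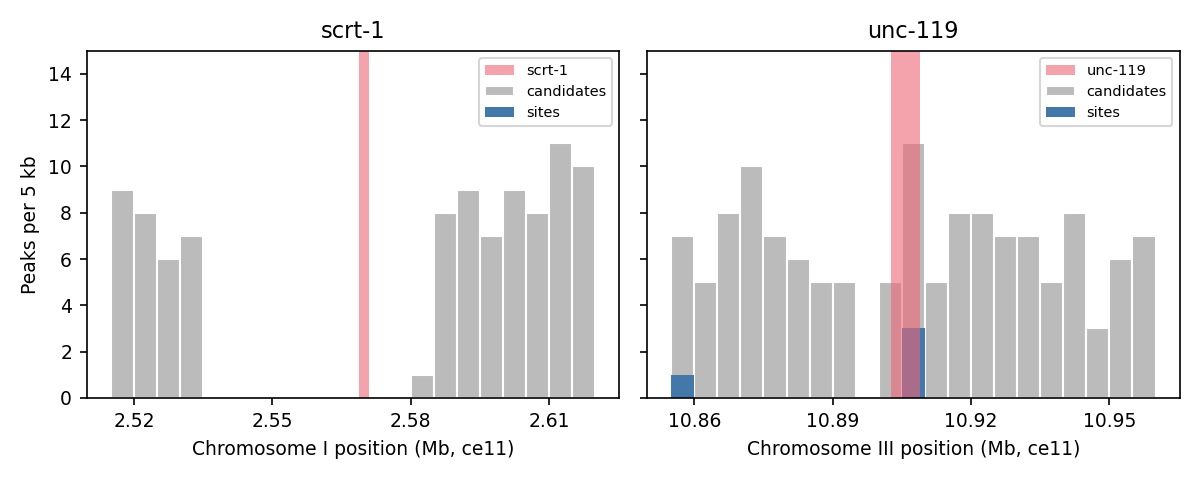
Ranked candidates (grey) and sites (blue) per 5 kb along chromosome I around scrt-1 and chromosome III around unc-119, with each gene shaded. Bins around scrt-1 hold 0 candidates, and the 3 sites at unc-119 fall in the bin of its 3 prime end.

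No promoter site was found at ces-1 and snai-1, the other Snail superfamily genes named beforehand, or at egl-1, the BH3-only cell death activator. ces-1 (I from 8633897 to 8636169) had no candidate in its promoter window. snai-1 (IV from 311484 to 313715) had 2 candidates, the better at an IDR of 0.489, and its nearest site lay 8.95 kb from its start (322504 to 322819, signal 183). egl-1 (V from 14431308 to 14432359) had 2 candidates, the better at an IDR of 0.514, and its nearest site lay 11.4 kb away (14443572 to 14443887, signal 83.4).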

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

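The tests in this part were chosen after the data were examined. The signal lies in data that the comparisons do not use: peaks of the comparison between the replicates that reach an IDR of 0.01 but are absent from the conservative list have a median signal of 148, against 94.6 for the sites that are in it. The strongest lies on X from 15810935 to 15811226, has a signal of 4525 (2342 in replicate 1 and 2314 in replicate 2) and sits at -861 bp from the start of the pseudogene Y7A5A.11. In all, 3 of them exceed the strongest conservative site, whose signal is 993. Of all these peaks, 90 are intergenic (80.4%) and 0 lie at small RNA genes. A median of 97% of the bases within 150 bp of their summits is soft-masked as repeat in the reference, against 19% for the sites. The reason for their absence is not given in the sources used here, and no biological explanation was tested.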

How the results depend on the processing

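Alternatives at IDR 0.001 and 0.05, with merged peaks, without sites at small RNA genes, with 50 or 300 bp around small RNA gene starts, the counts of sites from each replicate alone, and every alternative for the small RNA gene sites were chosen after the data were examined. Of 95 alternatives over 14 results, 69 counted as leaving the result unchanged, 20 moved it, 3 made it stronger, 2 weaker, and 1 reversed it. Unchanged meant an odds ratio with the same direction and side of the threshold, or a count within a fixed factor. For overlaps it meant a share above all random placements, and for correlations a value inside the main interval. Sizes could still shift: called gene lists going from 3 to 2 without replicate 1 counted as unchanged. The IDR of 0.01, planned as a stricter alternative to the assumed 0.05, equals that of the deposited lists and gave no value. The replicate overlap and signal agreement need both replicates, so leaving 1 out gave none. No paired analysis was possible because there is 1 group. The depth of the libraries is unknown, so what it limits cannot be stated. Where a value moved, fewer or more sites entered under the IDR and replicate alternatives, and otherwise the cause was not tested.

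The number of sites was 389 at an IDR of 0.001, 3201 at 0.05, and 522 to 564 without 1 replicate. Agreement of signal was 0.283 over all candidates and 0.625 over sites, which the IDR selects for agreement. Both promoter excesses held under every alternative (log2 odds ratios from 0.54 to 1.14 and from 0.57 to 3.15), as did that at small RNA genes (6.18 to 9.66). The X excess was not passed at an IDR of 0.05 (0.061) and without small RNA gene sites (0.063). CAGGTG had a log2 odds ratio of -0.40. It was lower and past the threshold with the optimal list (-0.73) and the whole peak (-0.41), ranged from -1.15 to -0.49 without 1 replicate (the lowest past the threshold), and reversed against the flanks of the same sites (0.54, p = 0.0817, Fisher's exact test). Fixed motifs called went from 3 to 1 at an IDR of 0.05, 1 with merged peaks, 6 against flanks, and 1 to 2 without 1 replicate. More frequent 6-mers went from 206 to 81 at an IDR of 0.05, 91 without small RNA gene sites and 689 against flanks. Gene lists called as higher went from 3 to 1 at an IDR of 0.001 and 5 at 0.05, where cell cycle and Notch and Wnt genes were added; with the nearest start within 5000 bp it was 2, histones and collagens. Bound genes went from 597 to 199 at 0.001, 1217 at 0.05, 979 with the nearest start within 5000 bp, and 286 to 292 without 1 replicate. Candidates per kb around scrt-1 fell from 0.237 to 0 within 10 kb.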

Other observations

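Chosen only after the values were seen were the non-coding genes of the next paragraph, the tests of the E-box at small RNA genes, of X without small RNA genes, of snoRNA gene copies, of genes without shared 30-mers and of unc-119 candidates, and the second window for ribosomal protein genes.

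Of 7764 genes annotated as ncRNA, 2.95% had a site within 100 bp of the start, sites also at tRNA or snoRNA genes included, as had 3 of 261 microRNA genes (1.15%, adjusted p = 0.122 against failed candidates, Fisher's exact test). Named ones include rpr-1, the RNA of RNase P, which trims tRNA precursors (I from 13463862 to 13464033, signal 308), and mrpr-1, the RNA of RNase MRP (II from 7200181 to 7200297, signal 272). They also include srpr-2.2 (230), srpr-1.2 (220), srpr-2.1 (146) and srpr-1.1 (144), annotated for the RNA of the signal recognition particle, and the microRNA gene mir-52 (IV from 14033813 to 14034203, signal 332). Among protein-coding promoters away from small RNA genes, strong sites in both replicates lay 74 bp upstream of atx-2, the ataxin-2 homologue (III from 10461228 to 10461405, signal 359), 29 bp upstream of ears-2, which encodes a glutamyl-tRNA synthetase (IV from 390392 to 390587, signal 346), and 60 bp upstream of idhg-1, an isocitrate dehydrogenase subunit gene (III from 4568653 to 4568829, signal 314). Of the tRNA genes, 37.3% were bound on X and 44.3% on autosomes (odds ratio 0.747, p = 0.0835, Fisher's exact test).

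The concentration of sites at tRNA and snoRNA genes may have a technical source, but GC content does not account for it: against failed candidates matched on GC alone the odds ratio was 88.1 (57.3 to 135). Binding through CAGGTG is argued against by its odds ratio of 0.642 (0.316 to 1.3) in sites at these genes against matched failed candidates. Reads shared between gene copies are argued against for snoRNA genes, since 16.9% (13.1 to 21.3) of the 343 with a sequence found once in the genome were bound, as were 18.5% (14.3 to 23.4) of the 297 without a 30-mer found elsewhere. At tRNA genes, identical copies alone do not account for it, since 26.6% (19.5 to 34.6) of genes without an identical tRNA gene were bound. Such genes were bound less often than genes with identical copies (odds ratio 0.431, 0.285 to 0.652). Reads shared between gene copies stay open as the whole source at tRNA genes. Of the 20 tRNA genes without a 30-mer found elsewhere, 0 (up to 16.8%) were bound. Of the 592 with such a 30-mer, 252 were bound (42.6%, 38.5 to 46.7), and these are all the bound tRNA genes. Signal at any highly transcribed gene cannot be told apart from specific binding without the control library. Within 100 bp of a start, 1.28% (0.0325 to 6.94) of ribosomal protein genes had a site, against 41.2% of tRNA genes. The upper limit was under 20.6%, the smallest share the prediction allowed there. The sites of ribosomal protein genes stand farther upstream, however. In the promoter window 16.7% (9.18 to 26.8) of these genes had one, against 48.5% of tRNA genes. That interval excludes the tRNA share but includes 24.3%, the smallest share the prediction allowed in this window.

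The excess on X goes with the location of tRNA genes. Away from small RNA genes the odds ratio of lying on X was 1.04 (0.877 to 1.24), which is consistent with tRNA genes, 45.1% of which lie on X, as its source. The design gives no biological contrast for it.

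The stretch without candidates around scrt-1 is unusual. Of the protein-coding genes, 2.0% (391) lie in one of the 37 stretches at least as long, under the share set beforehand for an ordinary gap. Such gaps thus occur elsewhere too, and this locus alone cannot decide whether its gap is an ordinary one. Its soft-masked share of 47.1% stood at percentile 83.2 and its GC content at percentile 74.1 of 1000 random stretches, so neither was extreme. That masked share was nevertheless above the random median of 32.2%. Soft-masking does not measure how well reads can be placed, so repeats stay open as a source. Extra transgene copies in the control library, which could remove peaks, remain open because the control was not analysed here, and the 54 candidates near unc-119, which the transgene also carries, do not decide it. How the lists were filtered is open too, and no biological explanation was tested.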
